A study of Mus musculus with 6 samples.

How the data were processed

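RNA of 6 mouse hearts, 3 wild-type and 3 with an EphB4 mutation, was labelled with biotin and hybridised to Affymetrix Mouse430_2 arrays, per the labels' protocols. The deposited values are log2 intensities made by the authors with RMA (robust multi-array average), per the submitters' processing notes, which give no version; the steps inside it are not given in the sources used here. The values ran from 2.42 to 14.79. No scanner files were used here, so the background correction could not be varied, and how far a probe set lay above background is not known. Groups and replicate numbers were taken from the sample titles, and the letters eI and eM from the start of the sample descriptions. The design text speaks of 6 mice, so each array was taken as 1 animal.

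Of 45101 probe sets, 64 Affymetrix controls were left out of all tests. Genes were named from the platform annotation supplied with the value table: 34945 probe sets named 1 gene, 932 named several and were not used for any gene, and 9160 were unnamed here. Symbols were set against the RefSeq gene table of the assembly GRCm38.p6 by gene ID; 34754 IDs matched and 0 symbols changed. Probe sets whose mean over the 6 arrays was in the lowest 40% (below 5.38) were left out, which left 27022. A gene was represented by its probe set of highest mean among those naming it alone, which gave 18193 genes, 13572 of them tested.

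Mutant and wild-type hearts were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) with no covariate. Single values and list means were compared with two-sided exact permutation tests. Intervals are 95% confidence intervals from the limma fit. Lists of genes for cell types, pathways and sources of carried-over tissue were tested with camera at a preset correlation of 0.01, adjusted over the 43 lists with at least 4 measured genes, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. The lists named 717 genes, of which 47 had no probe set used here under that name; 4 lists were too small to test, those of embryonic globins, skeletal muscle, fat, and sex-linked genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

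Named genes followed a rule set before the data were examined: Ephb4 and Efnb2 always; up to 12 genes per direction past the threshold; for places left over, genes of smallest p with at least 1.5-fold change and no overlap between groups; and up to 4 genes of smallest p from each list. Sex-linked genes were given only as a check of the sex of the hearts. Lbh, Nfic, Sparc and Wnt2 were chosen for the gene comparison after their values were seen, as were the genes named in the closing section. Of these, Lin28a, Trim71, Sall4, Prtg, Wnt2, Col2a1, Myocd, Lum, Mgp, Mb, Csf1r, Alas2 and Casq2 were taken from among the genes called between eM and eI hearts, not by size of difference. Kcnq1ot1, 2310067E19Rik and Ttn were named there for their small p, and Afp for its large difference. The liver, endoderm and epicardial genes given there were likewise chosen afterwards.

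Whether the shared replicate numbers pair the hearts was checked on deviations from the group means over all tested probe sets. Same-numbered hearts correlated at 0.18, 0.36 and 0.74, so by the rule used here the numbers count as paired, a pairing that comes from the titles alone; number 3 is also the pair with the letters eM. Differently numbered eI hearts correlated more strongly across genotypes, wild-type 1 with mutant 2 at 0.49 and wild-type 2 with mutant 1 at 0.47. Fits with the replicate number and with the letters as a block were run beside the main ones. Other alternatives were no filter and a stricter filter that left out 60% of probe sets, quantile normalization, centring each array on its median, eBayes with trend and robust, array weights, other thresholds, the letters as a random block, the eI hearts alone, other ways to choose a gene's probe set, and leaving out each heart in turn. The fit was tested on 20 simulated sets of arrays with 200 changed genes each among 13572. Of the calls, 0.3% were false without a block and 5.6% with the letters as a block. For a random 20-gene list shifted by 0.3, unadjusted camera p was under 0.05 in 20 of 20 sets, for an unshifted one in 0. Genes varied independently in these sets and the preset correlation was used, so they do not show how often camera calls lists of correlated genes by chance.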

Results

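Transcript levels were measured in whole mouse hearts on 6 Affymetrix Mouse430_2 arrays, 3 from wild-type mice and 3 from mice with a mutation of Ephb4. Ephb4 encodes a receptor tyrosine kinase of endothelial cells, and its main ligand is ephrin-B2, the product of Efnb2. The series title places the arrays in a study of signalling between ephrin-B2 of the heart muscle and its surroundings while the ventricular wall forms. The age of the mice, the sex of the hearts and the kind of mutation were not given in the sources used here. Without control probes, each array held 45037 probe sets as normalized log2 intensities, with medians between 5.89 and 6.01. The number of arrays, 3 per group, limited the precision of every comparison. Sample descriptions began with the letters eI for wild-type hearts 1 and 2 and mutant hearts 1 and 2, and with eM for wild-type 3 and mutant 3. What the letters stand for was not stated, so hearts are named by them below.

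Genotype did not separate the hearts, whereas the letters of the descriptions did. The first principal component held 60.4% of the variance and set wild-type 3 (34.1) and mutant 3 (52.6) apart from the eI hearts, which lay between -24.3 and -17.9. The second component held 18.4% and set wild-type 1 (33.8) apart from the other hearts. The highest correlation between arrays was that of mutant 1 with mutant 2 (r = 0.9958 across probe sets), and wild-type 3 was closest to mutant 3 (r = 0.9921). Signs of RNA quality moved with the letters too. The 3-prime minus 5-prime difference of the beta-actin control probes was 0.51 in wild-type 3 and 0.77 in mutant 3, against 0.28 to 0.41 in the eI hearts, and an 18S rRNA probe set read 12.34 and 11.62 against 9.75 to 10.42. The same difference of the GAPDH control probes set the letters apart less, at 0.03 and 0.12 against -0.10 to 0.02. Wild-type 1 had a lower upper quartile (8.05) than the other arrays (8.12 to 8.18) and a lower BioB hybridisation control (7.47 against 8.17 to 8.30).

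**Figure D1:**
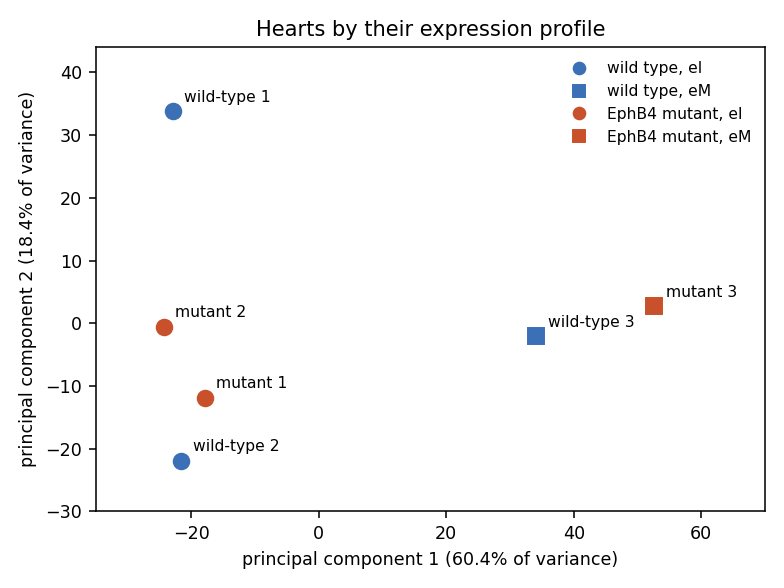
Each heart is placed by principal components 1 (60.4% of the variance, horizontal) and 2 (18.4%, vertical) of the tested probe sets, in arbitrary units, with colour for the genotype and shape for the letters of the description. Both eM hearts lie at the right (34.1 and 52.6), away from the eI hearts.

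Ephb4 transcript was present at the same level in both genotypes. Its only probe set read 8.03 ± 0.18 (SD, n = 3) in wild-type and 8.04 ± 0.11 (SD, n = 3) in mutant hearts. The difference was 0.01 log2 with a 95% confidence interval of -0.28 to 0.31 (two-sided exact permutation p = 0.9), and it was 0.01 within the eI hearts and 0.01 within the eM hearts. Since the kind of mutation is not stated, a transcript that persists neither bears out nor contradicts the labels. Efnb2 was likewise close between genotypes at its brightest probe set, at 9.94 ± 0.42 in wild-type and 10.12 ± 0.04 in mutant hearts (n = 3 each), a difference of 0.19 (exact permutation p = 0.7) that was 0.35 within eI and -0.14 within eM. Its other tested probe sets gave -0.01 and 0.12. A dim one that the filter left out gave -0.30 without overlap (exact permutation p = 0.1). The smallest two-sided p that 3 against 3 allows is 0.1.

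The comparison of mutant with wild-type hearts found no gene past the threshold. The genes that stood farthest apart without overlap between groups were higher in the mutant hearts, by 1.52 to 1.92-fold. They included Shox2, a homeobox gene of the sinus node and venous pole (5.64 ± 0.11 in wild-type, 6.29 ± 0.21 in mutant hearts, n = 3 each, 1.57-fold), and Fzd6, a Wnt receptor (7.90 ± 0.04 and 8.55 ± 0.30, 1.58-fold). Amacr, an enzyme of branched-chain fatty acid breakdown, differed by 1.92-fold (6.57 ± 0.70 and 7.51 ± 0.13), Eps8, an actin regulator, by 1.84-fold, and Myl1, a myosin light chain, by 1.63-fold (11.52 ± 0.49 and 12.23 ± 0.43). The other 4 were H3f3b (1.6-fold), 2810002D19Rik (1.59-fold), Pga5 (1.57-fold) and Eno2, the neuronal enolase (1.52-fold). Within the eI and eM hearts these log2 differences were 0.79 and 0.36 for Shox2, 0.81 and 0.36 for Fzd6, 0.90 and 1.02 for Amacr, 0.78 and 1.08 for Eps8, and 0.52 and 1.07 for Myl1. Shox2, 2810002D19Rik, Pga5 and Eno2 were dim, with wild-type means of 5.64, 5.93, 5.77 and 5.72, and the stricter filter left them out. Pga5 was raised mainly in mutant 2 (7.30 against 5.96 in mutant 1 and 5.99 in mutant 3). No gene that was lower in mutant hearts met this rule of at least 1.5-fold and no overlap. Of the genes chosen after their values were seen, Lbh, a transcriptional cofactor of the developing heart and limbs, had the smallest unadjusted p: 10.47 ± 0.04 in wild-type and 9.97 ± 0.10 in mutant hearts (n = 3 each, limma, adjusted p = 0.9997). Its difference was -0.50 log2, with -0.54 in eI and -0.41 in eM. Likewise chosen afterwards, Nfic differed by -0.40 and the matrix gene Sparc by -0.29 (12.81 ± 0.07 and 12.52 ± 0.04), each without overlap. Some genes gave different sizes by probe set: those of Fzd6 gave 0.13 to 0.66 and those of Eps8 0.12 to 0.88.

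In limma, 0 of 13572 genes and 0 of 27022 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.9997 for genes and 0.9999 for probe sets. At an unadjusted p under 0.05 there were 127 genes, 58 higher and 69 lower in the mutant, where 679 are expected by chance, and 316 probe sets against 1351 expected. Groups did not overlap at 596 genes, or 4.4%, where chance gives 10%. These chance values take the 6 hearts as exchangeable, but each genotype held 1 eM heart, and the hearts differed most by their letters. Other splits of the hearts into 3 and 3 gave 64 to 317 genes at a limma p under 0.05 with 1 eM heart per side. With both eM hearts on the same side they gave 543 to 2180. The low counts therefore do not show genotypes more alike than by chance. With the letters as a block, limma again called 0 genes (smallest adjusted p = 0.9974, 416 genes with an unadjusted p under 0.05), and within the 4 eI hearts it called 0. On simulated arrays with the spread of these data, the same fit recovered 71.3% of genes changed 2-fold and 12% of those changed 1.5-fold, and the fit with the letters as a block recovered 97.1% and 71.1%. Without mutant 2, limma called 2 genes, both linked to sex: Eif2s3y (5.87 log2 higher, adjusted p = 0.000156) and Xist (-5.11, adjusted p = 0.0066), and without wild-type 3 it called 1 probe set.

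**Figure D2:**
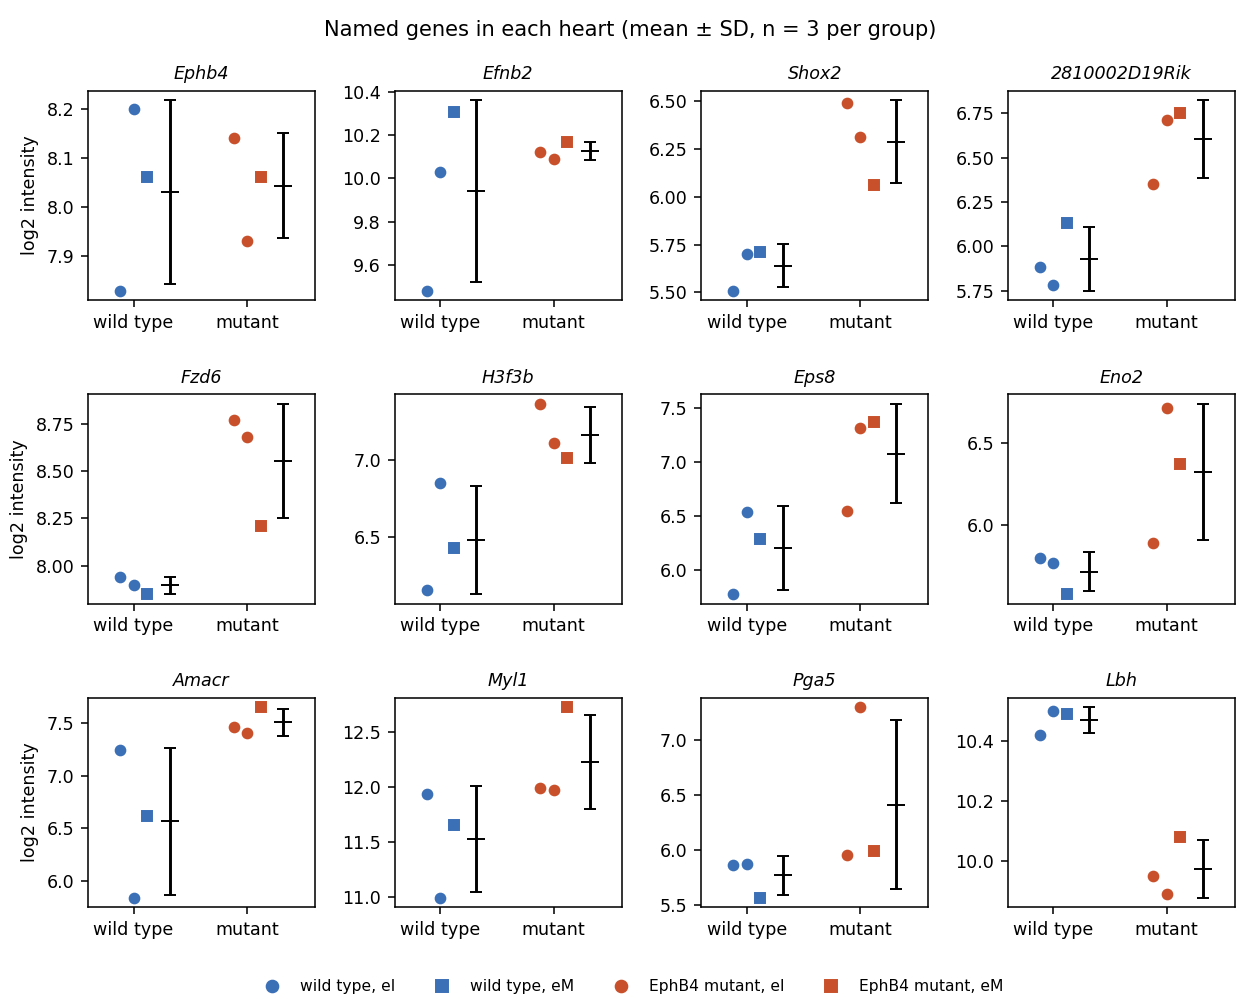
Log2 intensity of 12 genes in each heart, with the mean and SD of each genotype (n = 3) beside the points, colour for the genotype, shape for the letters of the description, and vertical axes that differ between genes and do not start at 0. Ephb4 lies at 8.03 in wild-type and 8.04 in mutant hearts, and Lbh at 10.47 and 9.97.

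The hearts carried sex-linked transcripts that differed between genotypes. Xist, transcribed from the inactive X chromosome of females, read 11.51 to 12.33 in the 3 wild-type hearts and 11.75 in mutant 2, but 6.73 in mutant 1 and 6.78 in mutant 3. The Y-linked Eif2s3y read 9.56 in mutant 1 and 9.58 in mutant 3, against 3.49 to 3.79 in the other hearts. Sex was therefore partly confounded with genotype, with no Xist-low heart among the wild-type hearts.

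Gene lists for cell types and pathways, written before the data were examined, were compared between the genotypes. Of 47 lists, 43 had at least 4 measured genes, and camera (limma, preset correlation of 0.01) called 2 higher and 1 lower in the mutant hearts. With an estimated correlation it called 0, and each of the 3 had an adjusted p = 0.985. Epicardial genes, markers of the outer layer of the heart, were higher: 15 of 16 genes had a positive difference, with a median of 0.32 log2 (list mean 8.39 ± 0.31 in wild-type and 8.66 ± 0.08 in mutant hearts, n = 3 each; limma camera adjusted p = 0.0003). Among them, Bnc1, a zinc finger gene of mesothelium, differed by 0.48 ± 0.15 (SE), the guidance gene Sema3d by 0.51 ± 0.17, Rspo1 by 0.42 ± 0.25 and the mesothelial Upk3b by 0.35 ± 0.22, none past the threshold alone. Mitotic genes were higher at 22 of 23 genes with a median of only 0.09 (10.56 ± 0.10 and 10.66 ± 0.23; adjusted p = 0.0041), with 0.26 for the kinase Aurka and 0.27 for the cyclin Ccna2. Liver genes were lower at all 6 measured genes with a median of -0.73 (6.89 ± 1.40 and 6.27 ± 0.85; adjusted p = 0.0069), such as the apolipoprotein Apoa2 (-0.74 ± 0.43) and the transport protein Ttr (-0.73 ± 0.58).

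These 3 calls did not hold in every kind of heart or test. The epicardial difference was 0.41 within the eI hearts and -0.01 within the eM hearts, the mitotic difference 0.01 and 0.28, and the liver difference -0.78 and -0.31. Besides camera with an estimated correlation, fry called 0 lists (smallest adjusted p = 0.995). No gene of any list passed with p adjusted over the list alone, nor over all genes tested. Exact permutation p of the list means was 0.4 for epicardial, 0.7 for mitotic and 0.5 for liver genes. Leaving out single hearts ended calls: the epicardial adjusted p was 0.143 without wild-type 2, the mitotic 0.261 without wild-type 1 and 0.497 without mutant 3, and the liver 0.598 without wild-type 2, 0.292 without mutant 3 and 0.0501 without wild-type 1. The mitotic mean difference was -0.03 without mutant 3, and the liver difference was 0.12 without wild-type 2, where camera's direction stayed down. With the Xist level as a covariate, an alternative chosen after seeing the data, the mitotic shift was -0.06 (adjusted p = 0.307) and the liver shift -0.28 (adjusted p = 0.108), while the epicardial shift was 0.23 (adjusted p = 0.00408 with the preset correlation). The number of lists called was 5 without wild-type 3, 9 without mutant 1, 6 without mutant 2 and 8 without mutant 3. With the replicate numbers or the letters as a block, camera also called fatty acid oxidation lower (adjusted p = 0.00554 with the letters, against 0.218 without). With an estimated correlation neither block called any list (adjusted p = 0.9955 for fatty acid oxidation with the letters and 0.993 with the replicate numbers).

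**Figure D3:**
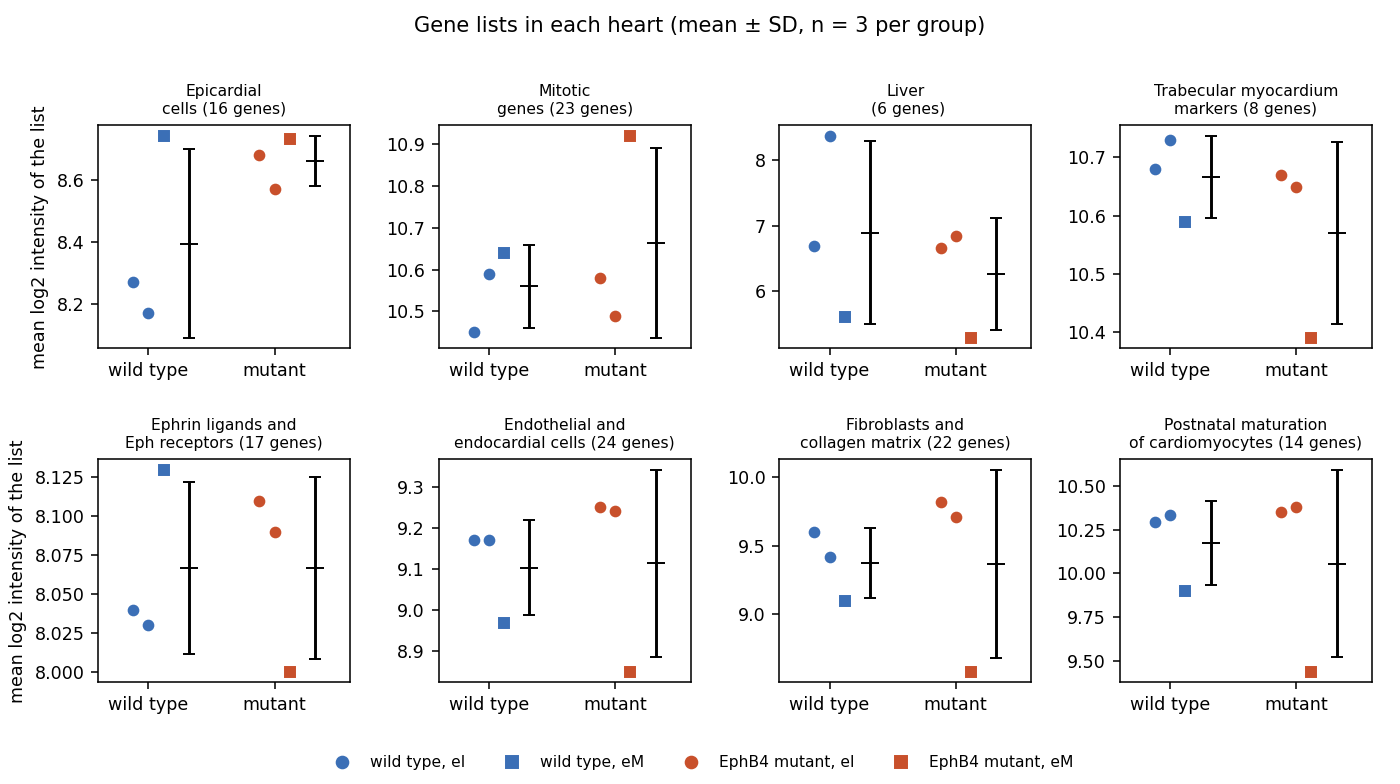
Mean log2 intensity of 8 gene lists in each heart, with the mean and SD of each genotype (n = 3) beside the points, colour for the genotype, shape for the letters of the description, and vertical axes that differ between lists and do not start at 0. Epicardial genes average 8.39 in wild-type and 8.66 in mutant hearts, with wild-type 3 at the level of the mutants.

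Signalling genes tied to ephrin and to the forming ventricular wall lay close together in both genotypes. The 17 measured ephrin and Eph genes had a median difference of 0.01 (8.07 ± 0.05 and 8.07 ± 0.06, n = 3 each), with Epha7 at -0.13 and Ephb1 at 0.31. Neuregulin and ErbB genes, which drive trabeculation, had a median of -0.05 over 8 genes, 2 of them higher: Nrg1 differed by 0.07 ± 0.12 (SE), Nrg2 by -0.28 ± 0.13, Hbegf by -0.08 and Erbb3 by -0.19. Notch genes had a median of 0.02 over 18, with Hes1 at -0.29, Nrarp at -0.14, Rbpj at 0.11 and Notch1 at -0.14. Medians were 0.00 for BMP and TGF-beta genes (Smad6 -0.17, Tgfbr3 -0.11), 0.04 for VEGF and angiopoietin genes (Kdr -0.22, Angpt1 0.10) and -0.10 for other paracrine growth factors of the heart, of which 5 of 16 were higher (Fgf9 -0.24). Wnt2, one of those growth factors, differed by 0.78 ± 0.61 and had the smallest unadjusted p once the letters were a block (limma, adjusted p = 0.9974), with 0.65 within eI and 1.04 within eM. Camera called none of these lists (adjusted p from 0.441 to 0.966).

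Heart muscle genes showed no called shift. Trabecular markers were lower at 7 of 8 genes with a median of -0.04 (10.67 ± 0.08 and 10.57 ± 0.16, n = 3 each; limma camera adjusted p = 0.283), with the natriuretic peptide gene Nppb at 12.81 ± 0.21 and 12.51 ± 0.06 and Cited1 at -0.29 ± 0.39 (SE). Compact wall markers had a median of 0.03 (Nkx2-5 0.17, Hey2 0.19). Medians were -0.05 for sarcomere and calcium handling genes (21 of 28 lower, Slc8a1 -0.29, Csrp3 -0.15), -0.02 for cardiac transcription factors, 0.05 for atrial and -0.03 for ventricular markers, -0.04 for stress and fetal genes (Fos -0.31) and -0.05 for cardiac jelly and its remodelling (Has1, a hyaluronan synthase, -0.29). Genes of postnatal maturation had a median of -0.07, intercalated disc and adhesion genes -0.02, and planar polarity and actin genes 0.02.

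Markers of the other cell types differed little between genotypes. Medians were 0.01 for endothelial and endocardial genes (Tie1, a receptor of vessel lining, 0.27 ± 0.10 (SE) and without overlap; Sox17 0.35 ± 0.18), 0.07 for endocardial markers, 0.02 for arterial and 0.02 for venous and coronary genes. Fibroblast and collagen genes had a median of 0.02, which joined a difference of 0.26 within eI to one of -0.52 within eM (Col5a2 -0.35 overall). Valve and cushion genes had a median of -0.03, smooth muscle and pericytes -0.03, macrophages and other leukocytes 0.13, erythroid cells 0.09, platelets and megakaryocytes -0.07, neural crest and Schwann cells 0.03, and lung and foregut epithelium -0.06. Camera called none of these lists in limma (adjusted p from 0.385 to 0.966).

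Genes of metabolism, growth and stress gave medians near 0. These were -0.09 for fatty acid oxidation (21 of 22 lower, Hadh -0.10, Acadvl -0.20), -0.03 for oxidative phosphorylation, -0.01 for glycolysis, 0.01 for DNA replication, 0.00 for kinase inhibitors of the cell cycle and -0.05 for p53 targets. Hypoxia targets had a median of 0.00, although Hmox1, a haem-degrading enzyme, was without overlap between groups at 7.57 ± 0.05 and 7.87 ± 0.13 (n = 3 each). The unfolded protein response had -0.05, interferon response -0.04, cytosolic ribosomal proteins 0.04, and immediate early and heat shock genes -0.01, with Hspa1b at 0.38 ± 0.12 (SE). Camera called none of them (limma, adjusted p from 0.218 to 0.995).

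Among lists that were not called, the sign of the camera test differed from that of the median for ephrin and Eph genes, fibroblasts, neural crest, DNA replication, and immediate early and heat shock genes, each with a median between -0.01 and 0.03.

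**Figure D4:**
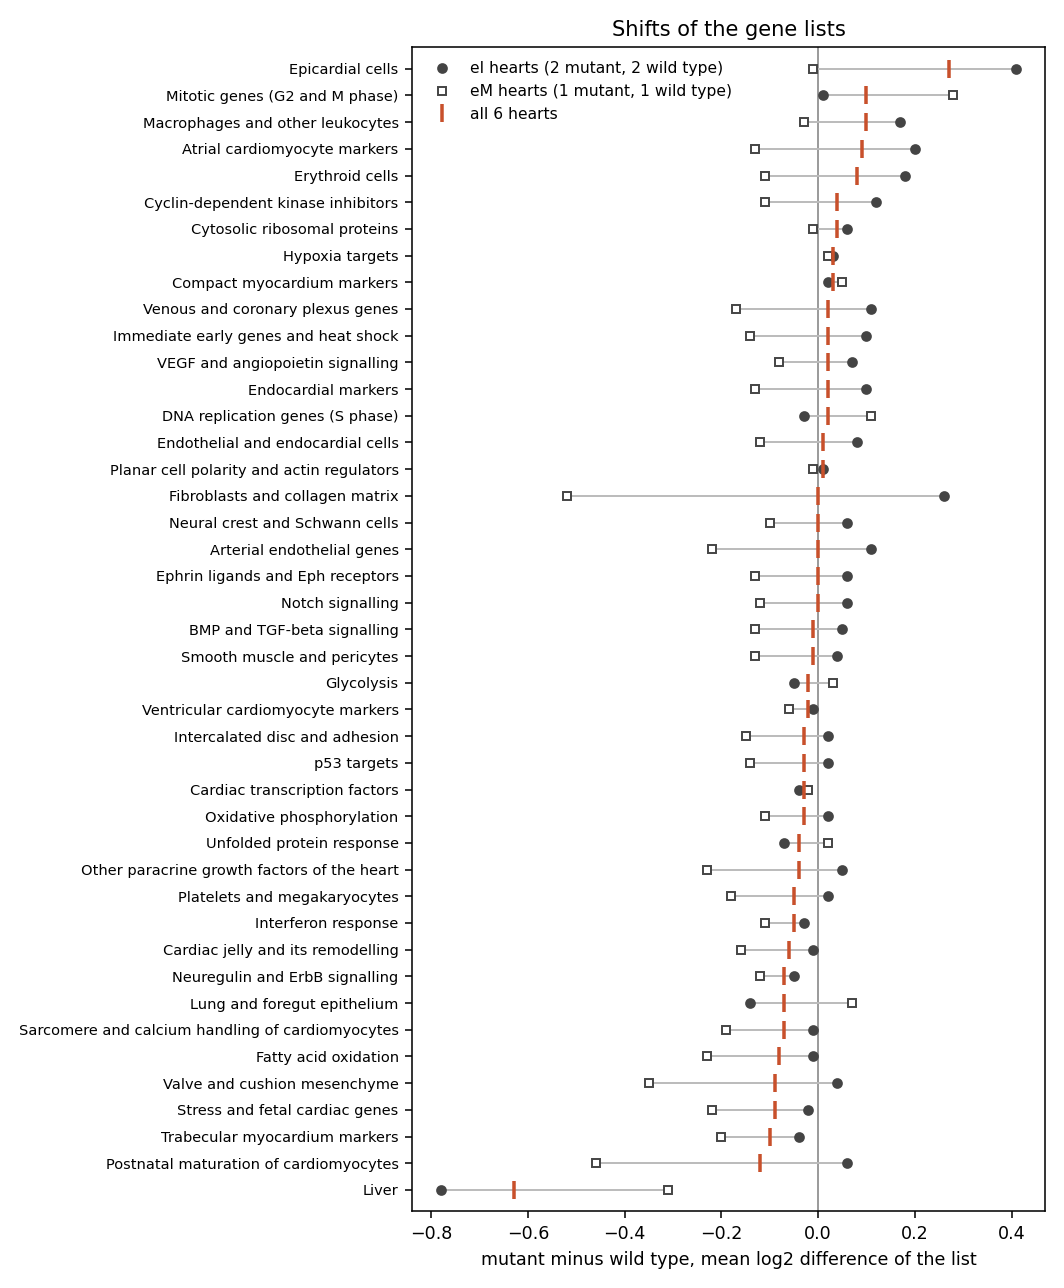
Mutant minus wild-type difference of the mean of each of the 43 gene lists (log2, horizontal), within the eI hearts, within the eM hearts and over all 6. Epicardial genes differ by 0.41 within eI and -0.01 within eM, and fibroblast genes by 0.26 and -0.52.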

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

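The tests of wild-type 1, over all hearts and within eI, and of Xist as a covariate below were chosen after the values they use had been seen; the other tests were written down before their results. The letters eI and eM were treated as groups under the same contrast, with 1 heart per genotype in eM. Each difference between them therefore rests on a single pair of hearts there. The spread between hearts that scales each gene's statistic comes from the eI hearts alone. Camera's p at the preset correlation then rests on the spread across genes, so it does not measure variation between hearts.

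By an interaction term in limma's camera (preset correlation), the mutant effect differed between eI and eM for 10 lists (adjusted p from 2.582e-10 to 0.03979), and for 0 with an estimated correlation (smallest adjusted p = 0.5831). The difference of the mean list effects, eM minus eI, was -0.78 for fibroblast genes, -0.52 for cardiomyocyte maturation, -0.42 for epicardial genes, -0.33 for arterial endothelial genes, -0.28 for other paracrine growth factors, -0.24 for immediate early and heat shock genes, -0.22 for fatty acid oxidation and -0.13 for oxidative phosphorylation. It was 0.26 for mitotic and 0.14 for DNA replication genes. Mutant 3 lay farther than wild-type 3 along the first principal component (52.6 against 34.1). The eM minus eI mean had the same sign for fibroblast (-0.8), maturation (-0.67), fatty acid oxidation (-0.52) and oxidative phosphorylation genes (-0.19). So it did for mitotic (0.26) and DNA replication genes (0.19). There, a differing mutant effect cannot be told apart from a single heart lying farther along that axis. The epicardial mean went the other way (0.32).

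The Y-linked genes Kdm5d and Uty had been left out of the tests as dim on average, yet were well above the wild-type hearts in mutants 1 and 3 at the probe set of largest difference; other probe sets of these genes differed less. Kdm5d read 8.15 and 8.09 there (wild-type mean 3.26 ± 0.11, n = 3), and Uty 7.19 and 7.37 (wild-type mean 3.21 ± 0.14, n = 3).

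Epicardial genes differed by 0.41 in eI and by -0.01 in eM between mutant and wild-type hearts. A difference in developmental age, read along the eM minus eI axis, predicted -1.4% of the eI shift. The eI differences of the other genes did not follow that axis (slope -0.018, correlation -0.04), which argues against a difference along it as the source. Whether the axis is one of age is not known, so a difference in age itself stays open. Wild-type 1 as the sole source stays open: without it 76.2% of the shift was left over all hearts (interval over the list's genes 48.7% to 100%) and 111.6% within eI (interval over genes 92.2% to 132.8%), which goes against it, as wild-type 2 (8.17) read below wild-type 1 (8.27), but that value rests on wild-type 2 alone and its interval from the spread between hearts ran from 15.6% to 207.6%. More epicardial cells in the eI mutant hearts may be a candidate explanation. A second epicardial list of 8 genes had a median eI difference of 0.26, at percentile 100 of 10000 random lists matched on mean level. Of its genes 6 were higher, such as Efemp1 at 0.89 and Krt7 at 0.72, while Anxa8 (-0.11) and Podxl (-0.16) were lower. The rise in eI is not specific to these cells, since fibroblast genes (0.26) and atrial markers (0.20) were also without overlap in eI. So were other lists, such as endothelial (0.08) and Notch (0.06) genes, and with so few hearts a lack of overlap is common by chance. The second list had a median of -0.21 in eM, the epicardial keratin Krt19 differed by -0.29 in eI, and the random lists do not carry the correlation between genes of a cell type. Sex stays open, since the shift left with Xist as a covariate (0.23) rests on the single Xist-high mutant heart, mutant 2. Its list mean was 8.57, against 8.27 and 8.17 in the eI wild-type hearts and 8.74 in wild-type 3, all Xist-high. Dissection was not tested, and the comparison of the genotypes cannot tell an effect of genotype apart from dissection or from the causes left open here.

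Liver genes were high in wild-type 2, with Afp at 11.83 against 7.77 to 9 in the other eI hearts, Apoa1 at 9.47 and Ttr at 9.62, while Alb, at 6.10 against 5.63 to 5.79, differed less. Carried-over liver or yolk sac endoderm may be a source, but a second endoderm list of 7 genes had a median excess of 0.11 there, at percentile 93.7 of 10000 random lists, short of the 95 set in advance. Apoa4 (2.13 above the other eI hearts) and Amn (0.83) were higher, and Mttp (-0.62) was lower. No biological explanation was tested, since a single wild-type heart is concerned.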

How the results depend on the processing

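The alternatives with Xist as a covariate, with a block and an estimated correlation together, with the 2 eM hearts alone, and with the eI hearts without wild-type 1 were chosen after seeing the data. Counts of changed genes and probe sets stayed at 0 under every other filter, scaling, variance model, weight and block; at an unadjusted p of 0.01 and 1.5-fold there were 9 probe sets and 3 genes, and leaving out single hearts gave 0 to 2 of each. The replicate block gave 0 genes and 0 probe sets and 4 lists, adding fatty acid oxidation, and changed no other call; with an estimated correlation, camera called 0 lists with either block, and the 3 list calls were lost at shifts of 0.27, 0.10 and -0.63. The number of called lists was 3, but 0 with an estimated correlation, 0 with fry, 2 to 9 leaving out single hearts and 6 in eI without wild-type 1, where the lone wild-type heart is assumed to vary like the mutant hearts. The epicardial shift of 0.27 lost its call with an estimated correlation (0.27) and fry (0.27) and was 0.16 to 0.44 leaving out single hearts. The mitotic shift of 0.10 lost its call with an estimated correlation (0.10) and fry (0.10), turned in eI (mean 0.01, camera's direction down), with Xist (-0.06) and in eI without wild-type 1 (-0.06), and was -0.03 to 0.19 leaving out single hearts. The liver shift of -0.63 lost its call with an estimated correlation (-0.63), fry (-0.63) and Xist (-0.28) and was -1.27 to 0.12 leaving out single hearts. Ephb4, at 0.01, turned to -0.01 with quantile normalization, -0.03 with array weights and -0.11 with Xist, and was -0.09 to 0.10 leaving out single hearts. Of 1065 alternatives for 57 single genes, none made a call, and the main fit held no call that could end. The sign turned in 23 of them, at 12 genes. These were Cited1 (0.09) and Acadvl (0.05) with array weights; Efnb2 (0.00), Epha7 (0.06), Slc8a1 (0.08) and Hadh (0.04) with the mean of all probe sets; Epha7 (0.16), Slc8a1 (0.26) and Hadh (0.01) with the probe set of largest spread; and Afp (0.53), Cited1 (0.03), Nrg1 (-0.01), Nrarp (0.01) and Acadvl (0.08) with Xist. Leaving out single hearts gave the ranges -0.04 to 0.37 for Efnb2, -0.03 to 0.32 for Hey2, -1.73 to 0.27 for Apoa1, -2.99 to 1.02 for Afp, -0.01 to 0.15 for Nrg1, -0.43 to 0.11 for Erbb3, -0.55 to 0.11 for Cited1 and -0.43 to 0.09 for Acadvl. In the 2 eM hearts alone, 22 of the 57 genes differed by more than 1 SD from the value over all hearts, and 8 of the 57 had the other sign, among them Sema3d (-0.03), Rspo1 (-0.35) and Upk3b (-0.24). The cause was not tested. The planned Xist covariate required both genotypes to hold Xist-high and Xist-low hearts and was not run as planned; Ephb4 has a single probe set, so there was no other to try. The 10 splits of the 6 hearts into 3 and 3, the real one among them, are too few for a share under 0.05. Counting the real split, 10 of 10 gave as many genes and 10 of 10 as many probe sets as the real one (0, highest other 0). As many lists came from 8 of 10, again counting the real split (3, highest other 15). The 2 splits with 15 lists put wild-type 3 and mutant 3 on one side, which points to the structure by letters; with the letters as a block 4 lists were called. Signal over background limits dim genes, which could not be judged from these values.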

Other observations

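The test of cardiomyocyte maturation in this part was chosen after its values had been seen; the globin and probe set tests were written down before their results. The eM hearts differed from the eI hearts far more than mutant from wild-type hearts did: with the genotype in the fit, limma called 607 genes higher and 790 lower in the 2 eM hearts than in the 4 eI hearts, of 13572. Among the higher genes were Lin28a, an RNA-binding protein of early embryos (4.67 ± 0.28 in eI, 7.30 ± 1.81 in eM), its fellow early regulator Trim71 (1.96 ± 0.26 log2, SE), Sall4, a zinc finger gene of stem cells (1.53 ± 0.25), and the early epithelial gene Prtg (1.71 ± 0.19). Lin28a read 6.02 in wild-type 3 and 8.58 in mutant 3. Wnt2 (1.63 ± 0.11), Col2a1 (2.09 ± 0.20) and the cardiac cofactor Myocd (1.13 ± 0.15) were higher too. So were Kcnq1ot1 (2.20 ± 0.11), 2310067E19Rik (2.04 ± 0.09) and the sarcomere gene Ttn (1.64 ± 0.11). Their unadjusted p in limma was smaller than that of Lin28a, Trim71, Sall4 and Prtg. Each passed at an adjusted p under 0.05.

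Among the lower genes in the eM hearts were genes of fibroblasts, blood and immune cells, of heart muscle and of liver. The liver gene Afp had the largest difference of the called genes, at -5.83 ± 1.02 (SE). It read 3.81 in wild-type 3 and 3.03 in mutant 3, against 7.77 to 11.83 in the eI hearts. The fibroblast proteoglycan Lum differed by -3.42 ± 0.44 (SE) and the matrix gene Mgp by -3.39 ± 0.48, the oxygen store Mb by -2.44 ± 0.37, the macrophage receptor Csf1r by -1.64 ± 0.17, the haem enzyme Alas2 by -1.96 ± 0.32, and the calcium store Casq2 by -1.88 ± 0.24. Heart muscle genes were not lower as a whole. Of 28 sarcomere and calcium handling genes, 4 were called higher and 4 lower in the eM hearts, with a median of -0.03. As lists, macrophages had a median of -1.14, erythroid cells -1, liver genes -0.99 (1 of 6 genes called lower) and fibroblasts -0.64. Fatty acid oxidation had -0.52 (15 of 22 genes called lower) and cardiomyocyte maturation -0.48. Mitotic genes had 0.18 and cardiac transcription factors 0.24. Camera called 6 lists higher and 11 lower with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.639). Mutant 3 lay beyond wild-type 3 in the same direction for maturation genes (9.44 and 9.90) and mitotic genes (10.92 and 10.64).

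The eM hearts differ from the eI hearts at many genes, and an earlier developmental age of the eM hearts is a candidate explanation. Maturation genes lay at percentile 0 of 10000 random lists matched on mean level, but these values had been seen first, so this does not test it independently. The adult-type globin Hbb-b2 relative to the embryonic Hbb-bh1 differed by -0.04 log2 between eM and eI, within the spread between hearts and with Hbb-b2 dim (5.41 to 6.48), so the globin switch leaves it open. Lower RNA integrity stays open too. Other probe sets of the called genes shared the sign of the called one at 86.3% (interval over genes 84% to 88.3%), but the share was 69.6% over all genes. No probe positions were used and a degraded transcript can fall at all its probe sets, so the bound set in advance does not decide. The beta-actin 3-prime excess was higher in eM, and that of GAPDH only slightly so. The meaning of the letters, a shared batch among the possibilities, stays open.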
